A study of Homo sapiens with 6 samples.

How the data were processed

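RNA polymerase II ChIP-seq peak lists were analysed for 3 conditions of SK-Hep1 cells, an established human cell line derived from a liver adenocarcinoma: control siRNA (siCtrl), siRNA against malic enzyme 2 (siME2), and the same siRNA with α-ketoglutarate added (siME2+αKG). The series holds 6 samples, 3 ChIP and 3 input. Each condition had 1 ChIP library and 1 input library. The titles of the siCtrl and siME2 samples carry the replicate number 2 and that of siME2+αKG carries none, and other libraries were not analysed here. The input libraries entered only through the peak caller, and no file of an input sample was used here.

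Per the labels' protocols, chromatin was precipitated with an RNA polymerase II antibody, and positions are on the hg19 build. The submitters' processing notes name Bowtie2 2.3.5.1 and MACS2 2.2.6, while the file headers name MACS 2.2.7.1; which of the releases made each value was not settled. Per the file headers, each list was called on a single ChIP library against its own input. Per the same headers, the caller was set to a p-value threshold of 1e-05, with 1 tag kept per position, model fold limits of 10 and 30, single-end tags of 150 bp and the larger of the 2 data sets scaled to the smaller. Estimated fragment lengths were 211, 201 and 221 bp for siCtrl, siME2 and siME2+αKG. In the deposited lists the pileup column is a signal, the number of extended ChIP fragments over the summit after that scaling. The deposited fold enrichment is a linear ratio of pileup to the local input background, each with 1 added. The deposited −log10 p and −log10 q columns are the caller's Poisson values, and q values were filled although the headers say that q was not calculated. Fold, p and q are the authors' values for each peak and were used here only to describe, rank or filter peaks within a list.

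After the authors' duplicate filter, the ChIP libraries held 13006504, 10445326 and 12955596 tags for siCtrl, siME2 and siME2+αKG, and the inputs held 15111004, 13079567 and 11656782. Duplicate tags made up 24.6%, 22.3% and 21.5% of the ChIP tags. Only the siME2+αKG ChIP pileup had been scaled down, by a factor of 0.900 computed from the tag totals. Dividing by it returned fragments that lay within 0.0055 of a whole number at every summit. The local background of a peak was recovered as (pileup + 1) / fold − 1.

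Peaks on chromosomes 1 to 22, X and Y were compared. A peak was shared when it overlapped a peak of the other list by at least 1 bp. Gene models came from GENCODE release 44 mapped to GRCh37. A gene had a promoter peak when a peak lay within 1 kb of any of its annotated transcription start sites, over 19794 protein-coding genes. Promoter heights were the fragments over the highest summit lying within 1 kb of a start site, per 1000000 filtered ChIP tags (the normalised height), and were compared as log2 ratios for genes with such a summit in both lists. Ratios carry 95% intervals from the exact conditional binomial (Clopper-Pearson) method, and shares carry exact Clopper-Pearson intervals. These intervals cover counting error only and compare libraries, not conditions. Heights were divided by the tag number alone, with no correction for the differing fragment lengths. With 1 library per condition there was no replicate check, no test between conditions and no p-value across genes.

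The comparisons, the definition of shared peaks, the alternative settings, the rule for named genes and 17 gene lists holding 390 genes were fixed before the data were examined. The rule took CCND1 and ME2 and, per comparison and direction, up to 12 protein-coding genes with the largest authors' fold among promoter peaks with −log10 q of at least 5 and no peak of the other list within 5 kb of the same start site. It also took up to 3 members of each list by the same order, and the 5 peaks of highest fold and the 5 widest peaks of each list. The lists covered the target genes, G1/S and G2/M cell cycle genes, replication-dependent histones, malate and TCA cycle enzymes, glutamine and α-ketoglutarate metabolism, α-ketoglutarate-dependent dioxygenases, RNA polymerase II and pause-release factors, p53 targets, ATF4 targets, hypoxia targets, immediate early genes, cytosolic ribosomal proteins, non-coding RNA genes, and markers of hepatocytes, of endothelial and mesenchymal cells and of leukocytes. A list's share of promoter peaks missing from another list was placed as a percentile among 10000 random gene lists of the same size matched on the decile of promoter fold.

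Several measures were added after the data had been seen. They are the median log2 height of each list, placed among 10000 random lists matched on height decile (39 list and comparison pairs), the same medians with a correction for promoter GC content, and height ratios of shared peaks limited to peaks that overlap 1 peak only in the other list. That last pairing gave the values reported for shared peaks, because the design had named no pairing and pairing every peak with the highest overlapping one put a long lower tail on the ratios where 1 wide peak met several narrow ones.

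The height ratios and list percentiles were tested on simulated data with known changes in 200 genes, drawn from the real summit heights. For siME2 over siCtrl, over 10683 promoters, intervals of unchanged promoters covered 0 in 96.5%, and simulated log2 changes of −1, −0.5, 0.5 and 1 came back as medians of −0.96, −0.53, 0.44 and 0.94, with intervals excluding 0 in 70.2%, 26.5%, 38.0% and 94.0%. For siME2+αKG over siME2, over 10440 promoters, the figures were 96.1% covered, medians of −1.05, −0.47, 0.51 and 1.01, and 74.5%, 28.0%, 44.9% and 88.0% excluding 0. Of 100 unchanged lists of 25 genes, 4% and 5% fell outside the central 95% of random lists. Those lists were random draws of independently simulated promoters, so this result checks the calculation only and not lists of related genes. Overlap counts were checked against bedtools 2.31.1. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

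Alternatives were a −log10 q of at least 5, lists of equal size, an overlap of 50% of the shorter peak, peaks within 1 kb merged first, all sequences in the files, promoter windows of 500 bp and 2 kb, unmatched random lists, height relative to the median and a flank of 50 kb at CCND1. A few genes met by the naming rule are not reported here. Reads, coverage tracks, motif analysis and differential peak calls were not used here.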

Results

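RNA polymerase II occupancy was profiled by ChIP-seq in SK-Hep1 cells to ask how knockdown of malic enzyme 2 (ME2), a mitochondrial enzyme that converts malate to pyruvate, and addition of α-ketoglutarate alter transcription of the cyclin D1 gene and of cell cycle genes. One peak list was available for each of siCtrl, siME2 and siME2+αKG, from 13006504, 10445326 and 12955596 filtered ChIP tags. The lists held 31710, 29201 and 28968 peaks on chromosomes 1 to 22, X and Y, covering 29.3, 23.8 and 26.1 Mb, with median lengths of 602, 554 and 611 bp. The lowest listed summits held 8, 7 and 8 fragments. There were no replicates, so each value below describes 1 library.

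Promoters of protein-coding genes carried 43.1% of siCtrl peaks (95% interval 42.6 to 43.7), 47.9% of siME2 peaks (47.3 to 48.4) and 46.4% of siME2+αKG peaks. A promoter peak was listed for 12302 genes in siCtrl, 12012 in siME2 and 11894 in siME2+αKG, and 11621 genes had one in all 3 lists. By the authors' fold enrichment, the leading siCtrl peaks lay at H3-3B, which encodes the replacement histone H3.3 (75.6-fold), at UBE2S, a ubiquitin-conjugating enzyme of mitotic exit (70.4-fold), at the U3 RNA gene SNORD3B-2 (69.9-fold), at POMZP3 (66.5-fold) and at DNAJC25 (64.7-fold). The siME2 list was led by SPTAN1 (66.2-fold), UAP1 (63.2-fold), H3-3B (63.0-fold), the matricellular gene CCN1 (60.5-fold) and the ribosomal protein gene RPS2 (58.9-fold). The siME2+αKG list was led by SNORD3B-2 (67.5-fold), a peak holding the start site of the transcription factor gene KLF6 (62.3-fold), the splicing factor gene SRSF7 (62.0-fold), TNFRSF12A (60.3-fold) and the stress-response gene GADD45A (59.9-fold).

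At CCND1, which encodes cyclin D1 (chromosome 11, 69455924 to 69469242, hg19), the promoter summit did not differ detectably between the libraries at this depth. The summit in the first exon held 98 fragments in siCtrl (a normalised height of 7.53 per 1000000 filtered ChIP tags), 73 in siME2 (6.99) and 90 in siME2+αKG (6.95). The log2 ratio of siME2 over siCtrl was −0.11 (−0.57 to 0.34). The ratio of siME2+αKG over siME2 was −0.01 (−0.47 to 0.46), whose sign turned when set against all promoters, and that of siME2+αKG over siCtrl was −0.12 (−0.55 to 0.31), whose sign turned likewise. These intervals leave room for a reduction to 0.675 or a rise to 1.27 of the siCtrl level in siME2. Just beyond the 3′ end of CCND1, the summits held 46, 32 and 42 fragments, with log2 ratios of −0.21 (−0.91 to 0.48) for siME2 over siCtrl and 0.08 (−0.62 to 0.79) for siME2+αKG over siME2.

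Listed peaks were fewer around CCND1 in siME2. Over the gene and 10 kb on either side, 9 peaks were listed in siCtrl, 6 in siME2 and 9 in siME2+αKG, and peaks covered 81.3%, 67.0% and 73.8% of the gene. The widest peak ran from 69454788 to 69463720 in siCtrl and from 69454777 to 69463232 in siME2, with a separate upstream peak from 69451001 to 69454613 and from 69450992 to 69454414. In siME2+αKG a single peak spanned both (69451398 to 69463136). With −log10 q of at least 5 the counts were 8, 5 and 6, and with 50 kb on either side 13, 11 and 14. The siME2 library was the shallowest, and the peaks that made the difference were low, such as that at 69471041 to 69471252 in siCtrl with 15 fragments.

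**Figure D1:**
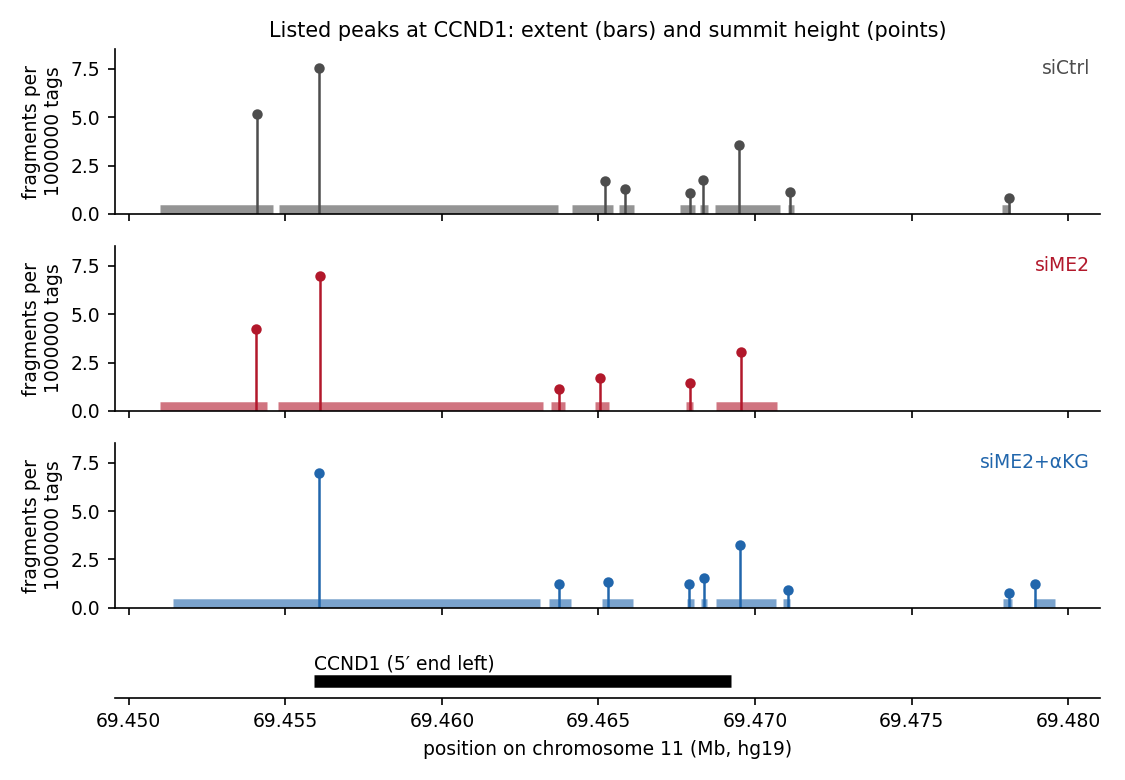
Peaks listed over CCND1 and 10 kb on either side in siCtrl, siME2 and siME2+αKG, by position on chromosome 11 (hg19, Mb). Bars mark peak extents and points mark summit heights in fragments per 1000000 filtered ChIP tags. The promoter summits stand at 7.53, 6.99 and 6.95.

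At the targeted gene itself, ME2 (chromosome 18, 48405450 to 48480627), each list held 1 peak over the first exon, from 48404911 to 48406316 in siCtrl. Its summit held 71, 56 and 63 fragments in siCtrl, siME2 and siME2+αKG (normalised heights of 5.46, 5.36 and 4.86). The log2 ratios were −0.03 (−0.56 to 0.50) for siME2 over siCtrl, −0.14 (−0.68 to 0.40) for siME2+αKG over siME2 and −0.17 (−0.68 to 0.34) for siME2+αKG over siCtrl, and the first of these turned sign when set against all promoters. A small interfering RNA acts on the transcript, so polymerase occupancy at ME2 does not check the knockdown or the labels.

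Between siME2 and siCtrl, the promoters listed in siCtrl and not in siME2 are named by authors' fold. MCM3, a subunit of the replicative helicase (peak in an intron near the start site, chromosome 6, 52149040 to 52149564), had 47 fragments and an authors' fold of 23.8 in siCtrl and no siME2 peak within 5 kb, although 37.7 fragments would have been its count at the siME2 depth. The next by fold were the histone H4 gene H4C11 (32 fragments), PCLAF, a partner of the replication clamp PCNA (32), the histone H4 gene H4C12 (33), the meiotic recombinase gene DMC1 (30) and the zinc finger gene ZNF350 (27). They were followed by the kinetochore scaffold gene KNL1 (28 fragments), the galanin gene GAL (33), AREGB (26), the endophilin gene SH3GL2 (26), FTCD (27) and the replicative DNA ligase gene LIG1 (25). H4C11, H4C12 and AREGB have near-identical copies, so their reads are uncertain. Of these 12 genes, 8 also had a promoter peak in siME2+αKG: MCM3 (37 fragments), LIG1 (33), KNL1 (27), GAL (22), PCLAF (21), AREGB (20), H4C11 (19) and H4C12 (19).

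In the other direction, the siME2 promoters with no siCtrl peak within 5 kb were weaker. They included the axonemal dynein gene DNAH7 (23 fragments), a start site of the spindle protein gene NUMA1 (19), PIFO (19), ZSCAN2 (18) and a start site of the DNA sensor gene IFI16 (18). CCDC74B (20), the metalloproteinase gene MMP19 (21), SYNDIG1 (16), the transporter gene SLC6A15 (16) and the ligand gene WNT2B (17) followed. NUMA1 and IFI16 had a siCtrl peak at another of their start sites. Of the 12 leading genes in this direction, 8 also had a promoter peak in siME2+αKG. Under this rule 436 genes were listed in siCtrl and not in siME2, and 132 in siME2 and not in siCtrl, of which 87 and 28 had a peak of the other list at another start site. A siME2+αKG promoter peak was present for 45.9% (41.1 to 50.7) of the 436 and for 48.5% (39.7 to 57.3) of the 132, and the intervals overlapped. Such shares count a peak at any start site of the gene, so they do not measure return of the missing peak itself. The deeper library was siCtrl, and these numbers carry no test between conditions.

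Among fixed-list members named by the rule, the cell cycle transcription factor genes E2F2 (13 fragments) and E2F1 (14), the spindle checkpoint kinase gene BUB1B (27), the histone gene H3C10 (24), the prolyl hydroxylase gene EGLN3 (23) and the surface antigen gene THY1 (16) had a siCtrl peak and none in siME2. All siCtrl peaks without a siME2 peak had a median of 13 fragments, and the lowest listed siME2 summit held 7. E2F2, E2F1 and THY1 were thus weak peaks. TRIB3, MTHFD2 and MXI1 lacked a siME2 peak at 1 start site and kept one at another, as KDM2B did for siCtrl. By the planned measure, the share of members whose promoter peak was missing, no list fell outside the central 95% of matched random lists. From siCtrl to siME2, 3 of 32 G1/S genes (percentile 92.4), 1 of 25 G2/M genes (79.2) and 2 of 19 replication-dependent histone genes (94.8) were missing. None was missing among 28 malate and TCA cycle, 31 RNA polymerase II and pause-release, 20 p53, 19 ATF4, 26 immediate early and 62 ribosomal protein genes with a siCtrl peak. One was missing among 18 glutamine and α-ketoglutarate metabolism genes, 31 dioxygenase genes and 22 hypoxia genes.

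Summit heights, a measure added after the data had been seen, placed the cell cycle and histone lists lower in the siME2 library than in the siCtrl library. The median log2 ratio was −0.36 over 24 G2/M promoters (21 lower, percentile 0 of random lists matched on height), −0.36 over 12 histone promoters (10 lower, percentile 0) and −0.23 over 29 G1/S promoters (23 lower, percentile 0.03), against −0.04 over all 10257 promoters. At single genes the ratio was −1.01 (−1.75 to −0.30) at CDK1, the mitotic kinase, −0.98 (−1.67 to −0.33) at PTTG1, which encodes securin, and −0.97 (−1.91 to −0.10) at PLK1, a mitotic kinase. The centromeric histone gene CENPA gave −0.96 (−1.68 to −0.28), the cyclin gene CCNB2 −0.82 (−1.57 to −0.11) and the kinase gene AURKB −0.64 (−1.27 to −0.03). Among G1/S genes, the interval lay below 0 at the replication licensing inhibitor GMNN (−0.97), at CCNE2 (−0.82), at the ribonucleotide reductase gene RRM2 (−0.70), at CDK4 (−0.60) and at MCM4 (−0.55), and above 0 at CDK6 (0.51). Among histone genes, H4C3 stood at −0.55 (−1.15 to 0.02) and H2AC8 at 0.37 (−0.21 to 0.96).

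Other lists stood closer to all promoters in siME2 over siCtrl, but the ATF4 targets of the amino acid response were nearly level with the G1/S list. Relative to all promoters these 2 lists stood at −0.18 and −0.19. The ATF4 targets had a median of −0.22 (17 of 19 lower, percentile 0.07, and 0.03 when GC content was matched too), with SHMT2 at −0.53 (−1.23 to 0.14) and DDIT4 at −0.43 (−0.88 to 0.02). Immediate early genes had −0.16 (18 of 24 lower, percentile 0.60, and 0.38 when GC content was matched too, but 3.24 and so within the central 95% of lists not matched on height), with EGR1 at −0.62 (−1.15 to −0.11). Ribosomal protein genes had −0.10 (47 of 62 lower, percentile 1.82, but 5.61 of lists not matched on height and 7.18 when GC content was matched too). Within the central range were malate and TCA cycle genes (−0.06, percentile 28.9), glutamine metabolism (−0.06, 34.6), hypoxia targets (−0.11, 9.74) and endothelial and mesenchymal markers (−0.11, 18.6). So were dioxygenases (−0.01, 67.0), RNA polymerase II factors (−0.04, 52.7) and p53 targets (−0.03, 54.9), which turned positive relative to all promoters. Across all 10257 promoters 162 intervals lay below 0 and 66 above, in total no more than the 96.5% coverage in simulated unchanged promoters would leave. Of these, 6 lay below 0 among the 24 G2/M and 5 among the 29 G1/S promoters.

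**Figure D2:**
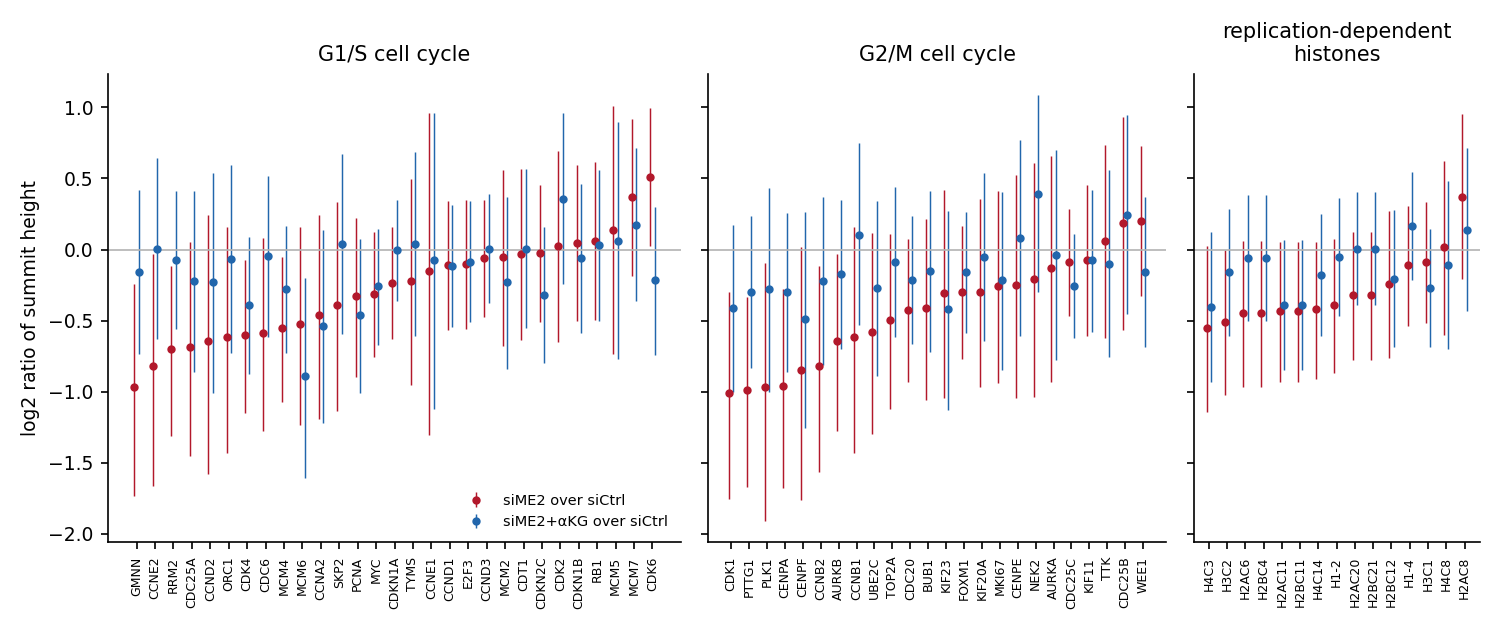
Log2 ratio of promoter summit height per 1000000 tags at G1/S, G2/M and replication-dependent histone genes, for siME2 over siCtrl (red) and siME2+αKG over siCtrl (blue). Points are single genes and bars are 95% intervals for counting error in 1 library per condition. CDK1 stands at −1.01 in siME2 and −0.41 in siME2+αKG.

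Between siME2+αKG and siME2, MCM3, LIG1 and KNL1, which had no siME2 promoter peak, were listed in siME2+αKG. The promoters with the largest fold and no siME2 peak within 5 kb were those of ZNF391 (39 fragments, 18.0-fold), MCM3 (37), the chromatin factor gene DPF1 (33), the clamp loader gene RFC3 (31), LIG1 and its neighbour ZSWIM9 (1 peak, 33), and the kinetochore gene SPC25 (30). The Notch ligand gene DLL4 (29), RDM1 (37), KNL1 (27), and PGAP4 with its neighbour RNF20, a histone H2B ubiquitin ligase gene (1 peak, 27), followed. All 12 also had a promoter peak in siCtrl, with 26 fragments at RFC3 and 33 at SPC25. Under the rule 190 genes were listed in siME2+αKG and not in siME2, of which 48 had a siME2 peak at another start site. Of the 190, 155 (81.6%, 75.3 to 86.8) had a siCtrl promoter peak at any start site. E2F2 (12 fragments), BUB1B (21), EGLN3 (16), H3C10 (15) and THY1 (16) were among the list members listed again. The median over all siME2+αKG peaks without a siME2 peak was 14 fragments.

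In the opposite direction, 309 genes were listed in siME2 and not in siME2+αKG, of which 59 had a siME2+αKG peak at another start site. A siCtrl promoter peak at any start site was present for 243 of the 309 (78.6%, 73.6 to 83.1), a share whose interval overlapped that of the other direction. The 309 genes were led by the flippase gene ATP9A (27 fragments, 14.3-fold), the CDK5 activator gene CDK5R2 (28), GAREM1 (22), a start site of ZFP90 (28), KAZN (21) and ZNF618 (21). The kinase gene JAK3 (24), the semaphorin receptor gene NRP2 (22), SYNGR1 (20), a start site of NUMA1 (19), SHKBP1 (19) and PIFO (19) followed. Of these 12 leading genes, 11 also had a siCtrl promoter peak at any start site, so the 2 directions were nearly alike in this count. FTO, an α-ketoglutarate-dependent RNA demethylase gene, had a promoter peak in siME2 (14) and siCtrl (16) and none in siME2+αKG. SDHA and KDM2B lacked a siME2+αKG peak at 1 start site only. No list passed the planned percentiles in either direction, the nearest being glutamine and α-ketoglutarate metabolism with 1 of 18 genes, the transaminase gene GPT, listed in siME2+αKG and not in siME2 (percentile 97.2).

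By summit height, the cell cycle and histone lists were higher in siME2+αKG than in siME2, against a median of −0.09 over all promoters. The G2/M list had a median log2 ratio of 0.28 (19 of 24 higher, percentile 100), histone promoters had 0.20 (9 of 12 higher, percentile 99.99, with a median of 0.10 after correction for GC content) and the G1/S list had 0.07 (18 of 29 higher, percentile 99.5). PTTG1 gave 0.69 (0.01 to 1.40), CCNB1 0.72 (−0.04 to 1.53), CENPA 0.66 (−0.05 to 1.40) and CDK1 0.60 (−0.15 to 1.38). GMNN gave 0.81 (0.07 to 1.59), CCNE2 0.83 (0.03 to 1.67) and RRM2 0.63 (0.04 to 1.24), while CDK6 gave −0.73 (−1.23 to −0.22). Across all 10097 promoters 293 intervals lay below 0 and 43 above, and of the latter 3 were among the 29 G1/S promoters and 1 among the 24 G2/M promoters. Immediate early genes had a median of 0.04 (12 of 22 higher, percentile 98.2, but 97.4 and so within the central 95% of lists not matched on height). Ribosomal protein genes (−0.01, percentile 97.1), ATF4 targets (0.00, 89.2), hypoxia targets (−0.02, 85.6), p53 targets (−0.01, 88.1) and RNA polymerase II factors (−0.03, 83.6) lay within the central range and turned positive relative to all promoters. The malate and TCA cycle list had −0.18 (23 of 28 lower, percentile 6.23), dioxygenases −0.11 (33.6) and glutamine metabolism −0.09 (42.4). Endothelial and mesenchymal markers had −0.08 (45.9), which turned positive relative to all promoters.

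Both sets of ratios share the siME2 library, so a value peculiar to that library would enter them with opposite signs. The 39 list medians were computed together, the random lists take genes as unrelated, and the percentiles describe these libraries only.

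**Figure D3:**
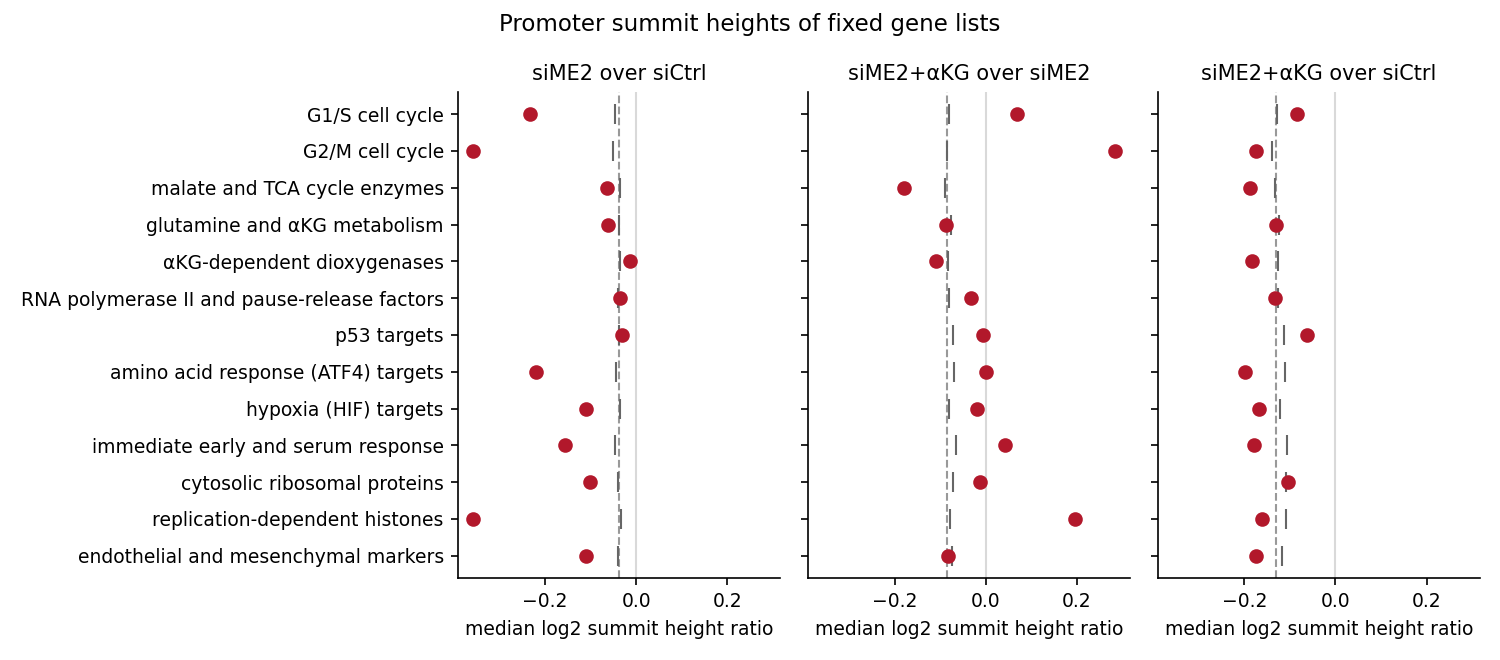
Median log2 ratio of promoter summit height for 13 fixed gene lists in siME2 over siCtrl, siME2+αKG over siME2 and siME2+αKG over siCtrl. Red points are list medians, grey ticks the median of 10000 matched random lists and dashed lines the median of all promoters. The G2/M list stands at −0.36, 0.28 and −0.17.

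Between siME2+αKG and siCtrl, no list stood apart from all promoters by height. The median over 10160 promoters was −0.13, and values are given relative to that shift. The G2/M list stood at −0.04 (percentile 26.2), the histone list at −0.03 (21.1) and the G1/S list at 0.05 (82.4), with a median of −0.08 before the shift was taken out. Relative medians were −0.07 for ATF4 targets (percentile 4.33), −0.05 for immediate early genes (6.08), −0.06 for malate and TCA cycle genes (14.4), −0.05 for dioxygenases (12.3), −0.04 for hypoxia targets (19.6) and 0.07 for p53 targets (85.5), which were at −0.06 before. Ribosomal protein genes stood at 0.03 (56.5; −0.10 before), and endothelial and mesenchymal markers at −0.04 (22.4). Glutamine metabolism (percentile 44.8) and RNA polymerase II factors (43.8) stood at the median of all promoters. MCM6, another helicase subunit gene, stood at −0.89 unshifted, and CDK1 at −0.41. Over all promoters 334 unshifted intervals lay below 0 and 17 above. Promoters listed in siCtrl with no siME2+αKG peak were led by DMC1, ESPN and its neighbour HES2 (1 peak, 28 fragments), a start site of RERE (27), ZNF350, SH3GL2, RALGPS1 (29), INSM2 (25) and LHX4 (26). C1orf159, the zinc finger gene PRDM16 and RAP1GAP had 24 fragments each. Those listed in siME2+αKG with no siCtrl peak included a start site of TSC22D1 (22), INTU (20), CADM2 (20), the cytokine gene IL1A (20), ZNF883 (20) and ZNF792 (20). Start sites of SLC4A8 (21) and FNDC3A (18), JAM2 (18), ANKDD1B (20) and DNAH7 (23) followed.

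Across the genome, most differences between lists lay outside promoters. Of the siCtrl peaks, 9861 (31.1%, 30.6 to 31.6) had no siME2 peak. Introns held 42.1% of them and promoters 15.4%, against 17.1% and 55.7% of the shared peaks. Their median authors' fold was 5.71, against 12.4 for shared peaks. Of the siME2 peaks, 4983 (17.1%) had no siCtrl peak and 6224 (21.3%) no siME2+αKG peak, and of the siME2+αKG peaks 7301 (25.2%) had no siME2 peak. The numbers without a peak between siCtrl and siME2+αKG were 9243 (29.1% of siCtrl) and 5474 (18.9% of siME2+αKG). At shared peaks that matched 1 to 1, the median log2 height was −0.01 for siME2 over siCtrl, −0.07 for siME2+αKG over siME2 and −0.09 for siME2+αKG over siCtrl.

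The return of siCtrl peaks with α-ketoglutarate was compared with its mirror. Of the 9861 siCtrl peaks not listed in siME2, 31.1% (30.1 to 31.99) overlapped a siME2+αKG peak. Of the 9243 siCtrl peaks not listed in siME2+αKG, 26.5% (25.6 to 27.4) overlapped a siME2 peak. The 2 shares were not on an equal footing. The siME2+αKG library held 12955596 filtered ChIP tags and its peaks covered 26.1 Mb, against 10445326 tags and 23.8 Mb for siME2. Of all siCtrl peaks, 70.9% overlapped a siME2+αKG peak and 68.9% a siME2 peak. The gap between the shares therefore cannot be credited to α-ketoglutarate. Both shares lay below those of all siCtrl peaks of the same fold decile, 47.9% and 44.4%. The peaks had been chosen for being missing from a list, and the same gap appeared in every direction. It therefore does not measure return. At −log10 q of at least 20 the order turned, with 68.5% (58.0 to 77.8) of 92 peaks against 73.6% (64.4 to 81.6) of 110, and the intervals overlapped. Among the 436 promoter genes of the naming rule, 45.9% (41.1 to 50.7) had a siME2+αKG promoter peak at any start site, against 54.4% (49.99 to 58.8) of 507 genes for the mirror. At another start site, 87 of the 436 had a siME2 peak and 98 of the 507 a siME2+αKG peak. These gene shares are therefore not the return of the missing peaks themselves. Merging all lists gave 37577 regions, of which 17809 were in all 3 lists, 2294 in siCtrl and siME2+αKG only, 2005 in siCtrl and siME2 only and 1118 in siME2 and siME2+αKG only.

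**Figure D4:**
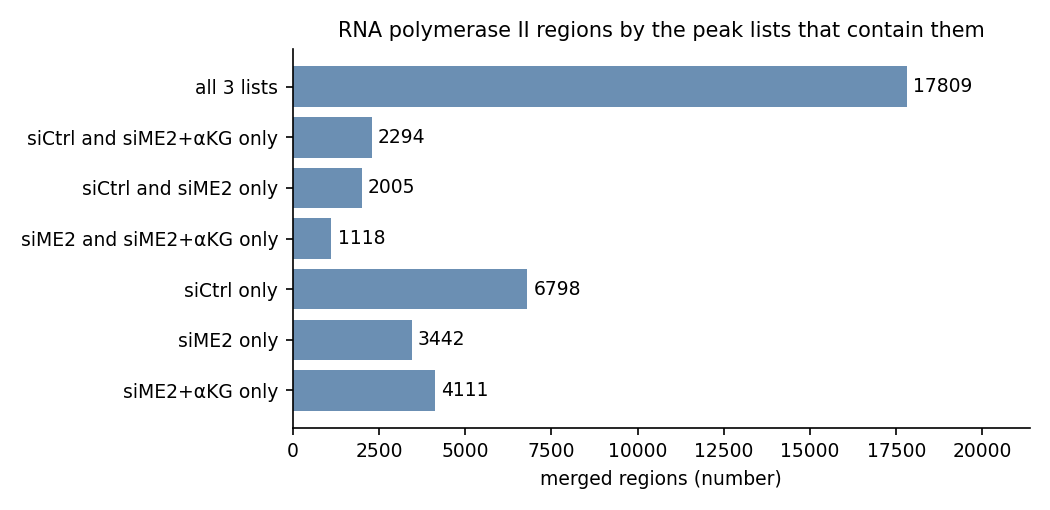
Number of merged RNA polymerase II regions by the peak lists that contain them, over 37577 regions on chromosomes 1 to 22, X and Y. The horizontal axis counts regions, and 17809 lie in all 3 lists.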

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

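The GC, culture and weak-peak tests below were chosen only after the result was seen, and the depth-thinning and local-background tests were set out beforehand.

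Peaks on sequences outside chromosomes 1 to 22, X and Y entered none of the main comparisons, only the alternative setting with all sequences. Of these, 51 were listed in siCtrl, 44 in siME2 and 53 in siME2+αKG, and no level in the input samples was analysed here.

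The median promoter summit of 24 G2/M genes was lower in the siME2 library than in siCtrl (−0.36) and higher in siME2+αKG than in siME2 (0.28). GC content was argued against as the whole cause: among random lists matched on height and GC content, the G2/M medians stood at percentiles 0 and 100. As a separate check, the GC-corrected medians were −0.34 and 0.23. With 1 library per condition, a difference between cultures or library preparations, including a different share of dividing cells at harvest, cannot be told apart from the treatment, and height-dependent enrichment was not tested separately, since matching on height had defined the pattern. The siRNA and the supplement remain untested explanations. The planned measure of missing peaks had put no list outside its range, though it cannot see a lower summit that stayed listed. A lower occupancy of mitotic genes after ME2 knockdown may therefore be taken only as a hypothesis.

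The 9861 siCtrl peaks without a siME2 peak were mostly weak: 0.715% were missing among 12865 siCtrl peaks with −log10 q of at least 20, against 31.1% of all, consistent with weak peaks lying near the calling limit. Thinning the siCtrl summits to the siME2 depth put 3022 under that limit, so that the observed number was 3.26 times the expected one. The same ratio ran from 3.09 to 5.25 over all 6 directions, those into deeper libraries included, so the model fell short everywhere. It takes each summit as its true mean although peaks were selected for passing, and it asks for no minimum width, which keeps the share due to depth and counting noise open. Whether the knockdown contributed was not tested.

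The authors' fold at ME2 was 13.6 in siCtrl, 32.1 in siME2 and 28.8 in siME2+αKG, although summit heights were close. The local background there was 4.30, 0.78 and 1.00 in the units of the deposited pileup, which was scaled down in siME2+αKG. The siME2 value equalled the genome-wide background of that list, 0.78, and so was no local measurement. The genome-wide value for siME2+αKG was 0.95. Among 10257 promoters, 727 had folds more than 2-fold apart between siME2 and siCtrl, and their median absolute log2 height ratio was 0.26, while that of the background was 1.24 (0.17 and 0.55 at the other promoters). This fits a difference in the input background as the source of most such gaps, which suggests that fold enrichment should not be read as a change between these lists. No biological explanation was tested.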

How the results depend on the processing

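The alternatives for list heights and for the pairing of shared peaks were chosen after seeing the data and the others beforehand. Of 210 planned results under other settings, 189 crossed no limit, 19 moved and 2 passed a limit that the reported value had not. Crossing no limit means that a count differed by at most 1.5-fold, a share stayed in its interval, or a list percentile stayed inside the central 95%, where it could still shift, as from 93.6 to 43.9 for immediate early genes in siME2 and not siCtrl with a 2 kb window. Merging peaks within 1 kb first, which joins broken peaks, lowered the numbers without a peak to 4907 (siCtrl against siME2), 2750 (siME2 against siCtrl), 3727 (siME2+αKG against siME2) and 3416 (siME2 against siME2+αKG), and the regions in exactly 2 lists to 1065 (siCtrl and siME2+αKG), 1058 (siCtrl and siME2) and 546 (siME2 and siME2+αKG). The share of siCtrl peaks missing in siME2 that were in siME2+αKG was 25.9% there (mirror 24.5%), 29.4% with −log10 q of at least 5 in every list, 33.5% with lists of equal size (mirror 28.5%) and 26.6% with 50% overlap (mirror 23.6%); the cause was not tested. With 50 kb on either side, CCND1 had 11 peaks in siME2 and 14 in siME2+αKG, from the wider span. Heights of shared peaks relative to their own median are 0 by construction, and pairing with the highest overlapping peak gave −0.071, −0.081 and −0.116. Leukocyte markers, with 2 genes or fewer, reached percentile 98.6 without matching (siME2 not siCtrl) and 98.7 with a 2 kb window (siME2+αKG not siME2). In the first case 1 of 2 genes was missing, against 1.32% of all genes with a siME2 promoter peak. That single gene set the percentile. For the 2 kb window the cause was not tested. The G2/M, G1/S and histone medians kept their direction in siME2 over siCtrl and in siME2+αKG over siME2 relative to all promoters, with GC correction and with members lacking 1 summit included, but the histone median in siME2+αKG over siME2 was 0.10 with GC correction. Depth limits single promoters: a simulated log2 change of −0.5 was seen in 26.5% of cases. No paired analysis was possible because each condition had 1 library.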

Other observations

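Single genes named here were picked after their values had been seen, while the gene lists and the rule for the widest peaks were fixed beforehand. Non-coding RNA genes had a peak within 1 kb of their start in every library: 12 of the 16 listed were in the annotation used, and all 12 had such peaks in each list. Such a peak can belong to a neighbouring gene. RNU4-1 and RNU4-2 both held 78, 59 and 82 fragments in siCtrl, siME2 and siME2+αKG. The U1 gene RNU1-1 had 12.99, 12.92 and 15.13 fragments per 1000000 tags in siCtrl, siME2 and siME2+αKG, the nuclear RNA gene NEAT1 had 9.15, 8.71 and 8.95, and MALAT1 had 6.77, 7.08 and 9.49. The U6 gene RNU6-1, transcribed by RNA polymerase III, had 4.38, 2.78 and 3.09, and RN7SK had 1.46, 1.149 and 1.24. The widest siCtrl peaks lay over LINC-PINT (25.3 kb), near PLEC with a summit downstream of coding genes (18.7 kb), and over AMOTL2 (17.1 kb), NEAT1 (17.1 kb) and MOK (17.0 kb). In siME2 they lay over SLFNL1 (17.1 kb), PLEC (16.8 kb), MIR23AHG (14.9 kb), NEAT1 (14.8 kb) and an intergenic stretch of chromosome 13 (14.2 kb), and in siME2+αKG over LINC-PINT (22.2 kb), the region at GPRC5A (18.3 kb), SLFNL1 (17.8 kb), NEAT1 (17.2 kb) and CCDC85B (15.4 kb). The siCtrl peak near PLEC (chromosome 8, 144984083 to 145002816) overlapped the siME2 peak there (144990824 to 145007648).

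Promoter peaks were also counted for the marker lists. Of 16 hepatocyte markers, 2 had a promoter peak in siCtrl and 1 in each of the other lists, and of 12 leukocyte markers 1 had one in siCtrl, 2 in siME2 and 1 in siME2+αKG. Of 19 annotated endothelial and mesenchymal markers, 12 had one in siCtrl, 11 in siME2 and 12 in siME2+αKG, and VIM, which encodes vimentin, had normalised heights of 10.76, 9.48 and 8.95. Among all protein-coding genes, 62.2%, 60.7% and 60.1% had a promoter peak in siCtrl, siME2 and siME2+αKG. The endothelial and mesenchymal counts were near those shares and do not mark a cell identity. At the lactate dehydrogenase gene LDHA, the log2 ratio was −0.60 (−1.08 to −0.13) for siME2 over siCtrl and 0.64 (0.17 to 1.12) for siME2+αKG over siME2. The pyruvate dehydrogenase gene PDHA1 gave −0.78 (−1.60 to −0.01) and 0.58 (−0.22 to 1.42), while the malate dehydrogenase gene MDH2 gave 0.51 (0.03 to 1.00) and −0.31 (−0.78 to 0.16). The elongation cyclin gene CCNT2 gave −0.55 (−1.19 to 0.06) and 0.65 (0.04 to 1.28).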
